A study of Mus musculus with 8 samples.

How the data were processed

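RNA of freshly sorted HSCs was extracted with a column kit for small samples, selected for polyA tails and made into libraries with a TruSeq kit, per the labels' protocols, and sequenced on an Illumina HiSeq, per the series' design text. There were 8 libraries, 2 technical libraries for each of 2 biological replicates at 4 months and 2 at 24 months. The technical pairing, the replicate numbers and the ages come from the labels.

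Each deposited file gives, per gene, a value named like a count and an FPKM value, and a table of the whole series repeats the same values for all 8 libraries. The build is mm9 and DESeq is named with no version or role, per the submitters' processing notes; the aligner and the counter are not given in the sources used here. The gene models merge Ensembl, UCSC and RefSeq transcripts under 1 symbol, per the file headers. The deposited values named like counts are not raw counts but a score: reads that the authors multiplied by 1 factor per library and rounded to whole numbers. This was tested on the values: 4 libraries skip whole numbers at a fixed spacing, and 0 of their gene values up to 100 fell on a skipped number. In the other 4, whose factor is under 1, 2 read counts round to some whole numbers, and these held between 1.83 and 2.01 times as many genes as adjacent ones. The factor of each library, estimated from the numbers skipped or doubled, lay between 0.617 and 1.839, with a largest error of 0.016% on 7 simulated libraries, which puts the reads per library between 22.3 M and 66.5 M. The deposited FPKM of a gene is that score times 1 constant per gene in every library, so it corrects for length and not again for depth. The table of the whole series also holds a log2 fold change and an FDR (an adjusted p-value) from the authors' own comparison of 24 over 4 months; which libraries entered it as replicates is not stated there. In it a gene is marked as higher or lower where its FDR is under 0.05 and the sum of its 2 mean FPKM values is at least 1, a rule that gave all 2635 marked genes when applied to the table.

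The test planned before the data were examined assumed raw counts. Because the values are scaled and rounded, the test written beforehand for files without counts was used. The scaled values of the 2 technical libraries were averaged, and log2(value + 0.5) of the 4 biological replicates was fitted in limma 3.58.1 (R 4.3.3) with age as the only term, an empirical Bayes prior with a trend on level, two-sided tests and Benjamini-Hochberg adjustment. Genes with a scaled value of at least 10 in at least 2 of the 4 replicates were tested, which left 18318 of 38172. Fold changes are old over young on the log2(value + 0.5) scale and understate the change of genes with low values. Means are given with the SD over 2 biological replicates. Whether a replicate came from 1 animal or from several is not stated, so p-values measure the spread between these samples.

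Gene lists (27) and marker lists (12) were fixed before the data were examined and matched by symbol, with joined symbols split. A list was tested with limma's camera, which compares its genes with all others, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists with at least 5 tested genes. It was tested again with the correlation estimated from the data. Fry, which tests a list for a shared direction against no change and not against other genes, was also run. So was its mixed test, which lets members go either way. With 4 samples the estimated correlation rests on few degrees of freedom. None of the lists passed with it. Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05. These had at least 5 CPM (counts scaled to equal library totals) in the higher age and both replicates of an age above both of the other. Unnamed models, small RNAs and immunoglobulin or T cell receptor segments were left out. It also took 2 to 4 of the 4 members with the smallest p in each list (1 where a single member was matched). Further genes were those of the sort (Kit, Ly6a, Slamf1 and Abcg2), and Cd34, Flt3 and Cd48, which the described sort did not use. The 5 most abundant rows and the most abundant member of each marker list completed it. Klf1, Rhag, the row of Hbb-b1 and Hbb-b2, Hmox1, Dsg2, Kdr and Col3a1 fall outside this rule and were chosen after their values were seen. Models named HNG, HAG or HND were counted as unnamed, a reading made after the data were examined. Of the 12 largest falls 1 gene is not reported here.

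The fit was tested on simulated reads of the 18318 genes for the comparison of old against young, drawn at the depth and factor of each library, with 200 genes changed by known folds in each of 20 simulations. When the variances were drawn from limma's own fitted prior, 23.8% of genes changed 2-fold were called, 70.2% of those changed 4-fold and 87.1% of those changed 8-fold, and 5.18% of calls were false on average. When each gene kept its own variance, the shares called were 56.8%, 85.3% and 96.2%, but 11.7% of calls were false on average, above the nominal 5%. A list of 40 genes shifted 1.5-fold was called in 20 of 20 simulations under either variance, and 1 and 0 of 400 random lists were called. The noise of each gene was drawn independently, so no simulated list held genes that vary together. In the data the estimated correlation ran from -0.0177 for the p53 list to 0.8973 for cytosolic ribosomal proteins. These simulations therefore do not show how often camera calls correlated lists falsely.

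Coordinates are those of the deposited files. Their starts were tested against the lengths of 493 micro RNA genes in a reference table of the GRCm38.p6 assembly: 483 lengths matched when starts count from 1 and 0 when they count from 0. No coordinate of that reference was used. Overlaps of the 24 genes with the largest changes with other rows were counted, and 3 of the 24 overlap a row that reaches over 0.1 of their own value. Reads shared between near-identical genes, such as ribosomal protein genes and their processed pseudogenes, histones or globins, may have been split by the counting. Library kits of this type do not mark strand unless a stranded version is used, which the labels do not state.

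Alternatives planned before the data were examined covered the test, scaling, filter, pseudocount, replicate number as a block, use of technical libraries, thresholds, set tests and leaving out each replicate in turn; a single prior variance, a robust prior and quantile normalization were added after the data were examined. Neither edgeR nor DESeq2 was used, since the values are not counts.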

Results

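The series measured polyadenylated RNA in haematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and give rise to all blood lineages, taken from C57BL/6 mice of 4 months (young) and 24 months (old). The cells were freshly sorted as SP-KSL-CD150+, that is, side population cells, which pump out a DNA dye, that carry Kit and Sca-1, lack lineage markers and carry the SLAM receptor CD150. The labels describe 8 libraries: 2 technical libraries for each of 4 biological replicates, numbered 13 and 14 at each age, so n = 2 per age. The labels do not say how many animals each biological replicate pooled. The deposited values of a library summed to between 40.7 M and 44.2 M after the authors' scaling, and the spacing of the values gave between 22.3 M and 66.5 M reads per library before it. The deposited table held 38172 genes, of which 18318 passed the filter on low values and were tested. The comparison implied by the labels asks which genes differ in expression between young and old HSCs, and all values below are scaled values of the authors averaged over the 2 technical libraries of a replicate.

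Old HSCs had higher levels of a set of genes with low values in young HSCs, and lower levels of Col1a1, Rgs7bp and a group of erythroid genes. Mab21l2, a developmental gene, rose from 11 ± 2.8 to 468.8 ± 32.9 (SD, n = 2 per age), a fitted fold of 41.4. Kcnb2, a voltage-gated potassium channel subunit, rose from 7.5 ± 2.1 to 253.5 ± 7.8, a fold of 32.3, and Gabra4, a GABA receptor subunit, from 13 ± 3.5 to 343.5 ± 61.5, a fold of 25.7. Tdrd9, an RNA helicase known from transposon silencing in the germ line, rose from 136.2 ± 8.1 to 2093 ± 354.3, and Gpr183, an oxysterol receptor, from 153 ± 63.6 to 2050 ± 158. In the other direction Col1a1, the alpha 1 chain of type I collagen, fell from 1350 ± 628.3 to 61.5 ± 4.9, and Rgs7bp, which anchors regulators of G protein signalling at the membrane, from 490.5 ± 6.4 to 41.5 ± 2.8. Col1a1 is also in the list of stroma markers, whose 9 tested genes all had a fitted change below 0.

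At a Benjamini-Hochberg adjusted p under 0.05 in limma, 467 genes differed with age, of which 368 were higher and 99 were lower in old HSCs. The median fold was 3.23 among those that rose, and the median ratio of old to young was 0.342 among those that fell. Of the 467 genes, 414 changed at least 2-fold. All 467 had both old replicates on the same side of both young replicates. With n = 2 per age a gene with overlapping replicates can hardly pass the test, so this follows from the selection and does not support the calls. Of all tested genes 42.1% showed this arrangement, which chance gives 33.3% of genes. Without old replicate 13 limma called 0 genes (3669 at an unadjusted p under 0.05), without old replicate 14 also 0 (1933), and without young replicate 13 or 14 it called 274 and 187.

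The 12 named genes with the largest rise also included Ripk4, Rasef, Rorb, Osmr, Spint1, Cldn5 and Aldh3a1. Osmr, the receptor subunit for oncostatin M, rose from 64.8 ± 10.3 to 817 ± 90.5 with a log2 fold change of 3.65 (SE 0.23, adjusted p = 0.00197). It lies on chromosome 15 from 6763577 to 6824313 in the mm9 build. Cldn5, a tight junction protein of endothelium on chromosome 16 from 18776940 to 18778355, rose from 144.2 ± 34.3 to 1580 ± 290.6. Aldh3a1, an aldehyde dehydrogenase, rose from 22 ± 1.4 to 228.8 ± 24.4. Mab21l2 on chromosome 3, from 86349503 to 86352205, lies inside the span of the more abundant Lrba on the opposite strand, Gpr183 overlaps Ubac2, and Cldn5 overlaps 2 unnamed models, so part of their reads cannot be assigned without strand information. Other genes among the largest falls were Sparc, Slc4a1, Spnb1, Abcg4, Cd86, Synpo2, Add2, Zan and Kcnk12. Sparc, a collagen-binding matrix protein, fell from 447.2 ± 126.9 to 68.2 ± 1.8, and Cd86, a costimulatory ligand of antigen-presenting cells, from 274.8 ± 38.5 to 73 ± 3.5. Slc4a1, Spnb1 and Add2 encode proteins of the red cell membrane or its skeleton.

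**Figure D1:**
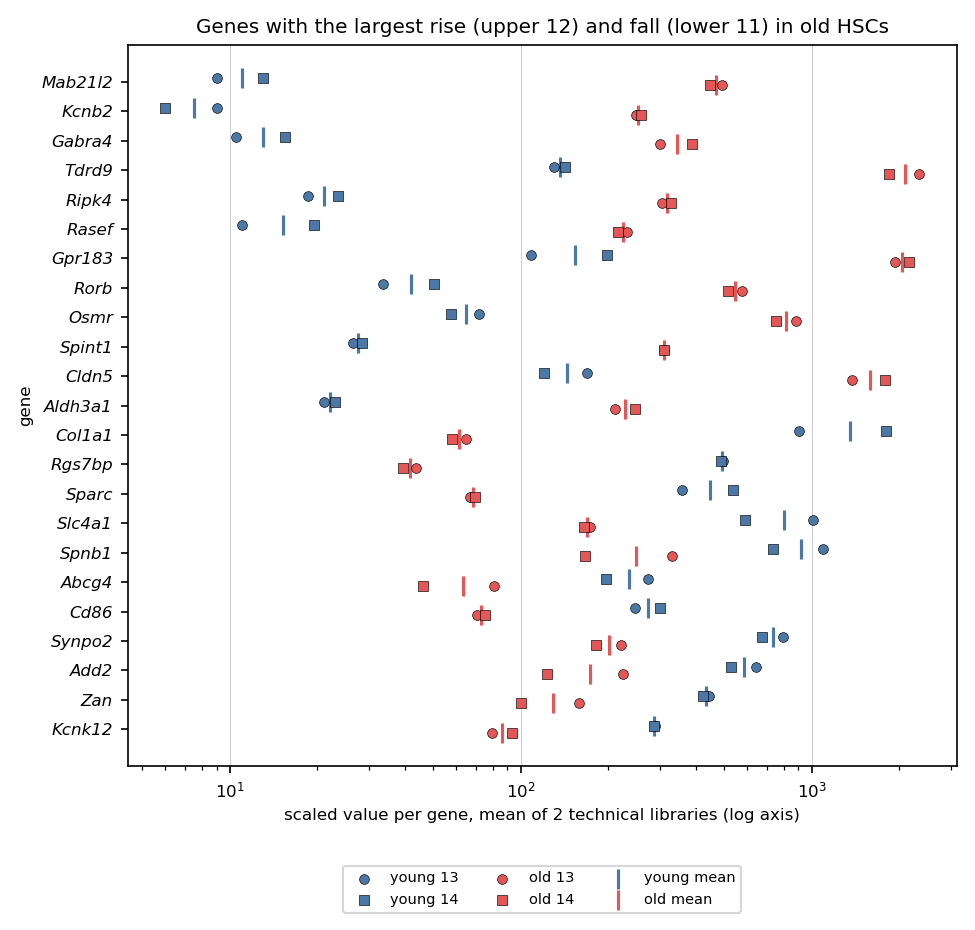
Scaled values (log axis) of the 12 named genes with the largest rise and 11 with the largest fall in old HSCs, with 1 point for each of the 4 biological replicates and a vertical tick at the mean of each age. For every gene shown both old replicates lie on one side of both young replicates; Mab21l2 has the largest fold at 41.4 and Col1a1 the lowest ratio of old to young at 0.0485.

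Most genes used to define stem cells had a fitted change above 0 in old HSCs, and few of them passed the test. Of 35 tested genes of the HSC identity list, 4 rose and 0 fell, 10 rose when adjusted over the list alone, and 33 had a fitted change above 0. Slamf1, which encodes the CD150 used in the sort, rose from 1666 ± 97.9 to 3129 ± 65.1, Procr, the protein C receptor EPCR, from 3386 ± 462.4 to 6054 ± 539.2, and Rarb, a retinoic acid receptor, from 655 ± 40.3 to 1735 ± 241.5. The list lay above other genes by limma's camera with a preset correlation (adjusted p = 6.39e-07), and did not pass with an estimated correlation (adjusted p = 0.299). Fry, which tests the list for a shared direction against no change, gave an adjusted p = 0.0878, and fry's mixed test an adjusted p = 0.0115. The other genes behind the sort had higher means in old HSCs, and none of these passed the test. Kit was 55670 ± 1007 in young and 60887 ± 4331 in old HSCs. Abcg2, the dye pump of side population cells, was 4624 ± 144.6 and 5899 ± 1058, and Ly6a, which encodes Sca-1, was 2597 ± 33.6 and 4542 ± 1447. The sort as described did not use Flt3, Cd34 or Cd48. Flt3, a receptor that marks multipotent and lymphoid progenitors, fell from 2196 ± 3.2 to 728.5 ± 106.1 (adjusted p = 0.00558), and Cd34 fell from 13919 ± 787 to 7305 ± 1322 (adjusted p = 0.0456). Cd48 was 195 and 779.5 in the young replicates and 125.5 and 280.5 in the old ones, and did not pass.

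Of 42 tested genes that earlier work on HSC aging had named, 36 rose and 0 fell, and 40 rose and 2 fell when adjusted over the list alone. This list was compiled from general knowledge and may derive in part from these samples, so it is not independent evidence of a direction. Slamf1, Selp, Vwf, Itgb3, Matn4, Dsg2, Neo1, Osmr, Mt1, Mt2 and Aldh1a1 belong both to it and to other lists. Their rises in those lists are the same observations and not separate themes. Selp, the platelet and endothelial adhesion molecule P-selectin, rose from 2412 ± 178.5 to 12954 ± 680.6, Clu, an extracellular chaperone, from 1030 ± 3.5 to 5098 ± 129.4, and Matn4, a matrix protein, from 408.8 ± 78.8 to 3176 ± 84.5. Camera gave an adjusted p = 3.56e-46, and an adjusted p = 0.299 with an estimated correlation. Of 39 megakaryocyte and platelet genes 4 rose and 1 fell, with 9 and 1 when adjusted over the list alone. Vwf, the clotting factor made by megakaryocytes and by a platelet-biased class of HSCs, rose from 12448 ± 2062 to 37894 ± 4009, and Itgb3, the beta 3 integrin, from 6341 ± 554.4 to 16305 ± 1584, whereas Gata1, a transcription factor of megakaryocytes and red cells, fell from 1733 ± 176.1 to 821.2 ± 115.6. The camera call of this list was marginal (adjusted p = 0.0439, and adjusted p = 0.759 with an estimated correlation) and it was lost with limma-voom (0.0514), median-ratio factors (0.0503) and the higher-numbered technical libraries (0.0686), and without old replicate 14 (0.0776) or young replicate 13 (0.968). Markers of mature megakaryocytes and platelets did not pass, with Pf4 at 1914 and 3222 in young and 2194 and 2760 in old HSCs.

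Genes of cell division had fitted values below 0 in nearly every member, mostly by small amounts. Of 44 tested G2/M genes all 44 had a fitted change below 0, with a median log2 fold change of -0.53. Only 1, Ect2, a regulator of cytokinesis, fell in the test over all genes, from 1989 ± 121.3 to 1128 ± 101.1, and 39 fell when adjusted over the list alone. Kif2c, a mitotic kinesin, was 1526 ± 21.2 in young and 971.2 ± 114.2 in old HSCs (adjusted p = 0.095). Of 41 G1/S genes 38 lay below 0 with a median of -0.38, 0 passed in limma or limma-voom over all genes with 25 at an unadjusted p under 0.05, and 14 fell and 1 rose when adjusted over the list alone. In this list Uhrf1, which recruits the maintenance DNA methyltransferase, was 8842 ± 415.8 in young and 5543 ± 425.7 in old HSCs, and Ccnd1, cyclin D1, was 4073 ± 390.7 and 7067 ± 1264. The 20 tested replication-dependent histone genes all lay below 0 with a median of -1.51, and Hist1h2ac and Hist1h2bg fell. Camera gave an adjusted p = 4.15e-27 for G2/M, 2.09e-16 for G1/S and 1.64e-13 for histones, and an adjusted p = 0.299 with an estimated correlation for each of these lists. Histone messages mostly lack a polyA tail and were measured at low values here, with Hist1h2ac at 118 ± 2.1 in young and 25.8 ± 10.3 in old HSCs.

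Chromatin and ribosome assembly genes had fitted values mostly below 0, and no single gene of these lists passed the test. Of 87 DNA methylation and chromatin regulators 71 lay below 0 with a median log2 fold change of -0.17, and of 60 ribosome biogenesis genes 49 lay below 0 with a median of -0.11. Camera gave an adjusted p = 1.24e-06 for the first list and 0.000416 for the second, and an adjusted p = 0.635 and 0.299 with an estimated correlation. For both lists 0 genes passed in limma, or in limma-voom, over all genes tested or when adjusted over the list alone in limma, with 8 and 1 at an unadjusted p under 0.05. The smallest p in the chromatin list belonged to Ezh1, a histone H3K27 methyltransferase, with 3325 ± 112.4 in young and 5278 ± 21.6 in old HSCs (adjusted p = 0.0578). Its paralog Ezh2 was 5256 ± 38.9 and 3503 ± 521.1 (adjusted p = 0.128). Nolc1, a nucleolar protein, was 7458 ± 450.4 and 5496 ± 1216, and Utp20, of the small subunit processome, was 5676 ± 88.4 and 4620 ± 420. Among the 22 tested quiescence genes and CDK inhibitors only Ndn, a growth suppressor, rose, from 1291 ± 115.6 to 2574 ± 294.5, Cdkn1c, the CDK inhibitor p57, was 1219 ± 81 and 1890 ± 280.4 without passing, and the list had an adjusted p = 0.963, with 0.00602 downward without young replicate 13 and 0.0423 upward without young replicate 14.

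Some erythroid and lymphoid genes were lower in old HSCs. Of 33 tested erythroid genes, with a median log2 fold change of -0.347, 11 fell and 1 rose, with 15 and 1 when adjusted over the list alone. Ermap, an erythroid membrane adhesion protein, fell from 2502 ± 126.6 to 793.5 ± 260.2, Klf1, the master transcription factor of red cells, from 841.2 ± 30.1 to 336.2 ± 73.9, and Rhag, a Rhesus-associated ammonium channel, from 686.2 ± 6 to 299.5 ± 14.8, while the metallothionein Mt2 rose. Camera gave an adjusted p = 9.59e-13, and an adjusted p = 0.299 with an estimated correlation. No globin row passed: the row of Hbb-b1 and Hbb-b2 was 627.5 and 542.5 in young and 353 and 674 in old HSCs. Of 42 lymphoid priming genes 2 fell, Flt3 and Satb1, and 0 rose, with 6 and 1 when adjusted over the list alone. Satb1, a chromatin organiser of lymphoid cells, fell from 601.2 ± 121.3 to 226.5 ± 27.6. The lymphoid list had an adjusted p = 0.000356, an adjusted p = 0.662 with an estimated correlation, and 0.41 without young replicate 14.

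Of 32 granulocyte and monocyte genes 0 passed in limma or limma-voom over all genes tested, with 7 at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. The list lay low by camera (adjusted p = 0.00349, and adjusted p = 0.759 with an estimated correlation), but without young replicate 14 its direction turned to higher in old HSCs (adjusted p = 0.0423), and without old replicate 13 it did not pass (0.344). Its smallest p belonged to Cd33, a sialic acid-binding receptor, with 70.5 and 117 in young and 13.5 and 27.5 in old HSCs (adjusted p = 0.0601), and to Csf2rb, the common beta receptor chain, with 942 and 1550 against 455 and 595.5 (0.0749). The neutrophil markers had all 11 tested genes below 0, with a median log2 fold change of -2.506 and summed values of 5814 in young 13, 14945 in young 14, 467.5 in old 13 and 6569 in old 14. Mpo, the myeloperoxidase of granulocyte progenitors, was 3598 in young 13, 27762 in young 14, 4428 in old 13 and 10022 in old 14. The immediate early and dissociation stress list had 1 of 47 genes, Gadd45g, that rose from 232.8 ± 12.4 to 588.2 ± 6.7. Hspa1a, a heat shock protein, was 16.5 and 151.5 in young and 5.5 and 6.5 in old HSCs. The stress list had an adjusted p = 5.56e-05 downward, an adjusted p = 0.759 with an estimated correlation, and a turned direction without young replicate 14 (adjusted p = 0.213), and it did not pass without old replicate 13 (0.159). Young 14 exceeded young 13 by a median log2 difference of 1.53 in the stress list and 1.43 in the granulocyte list.

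**Figure D2:**
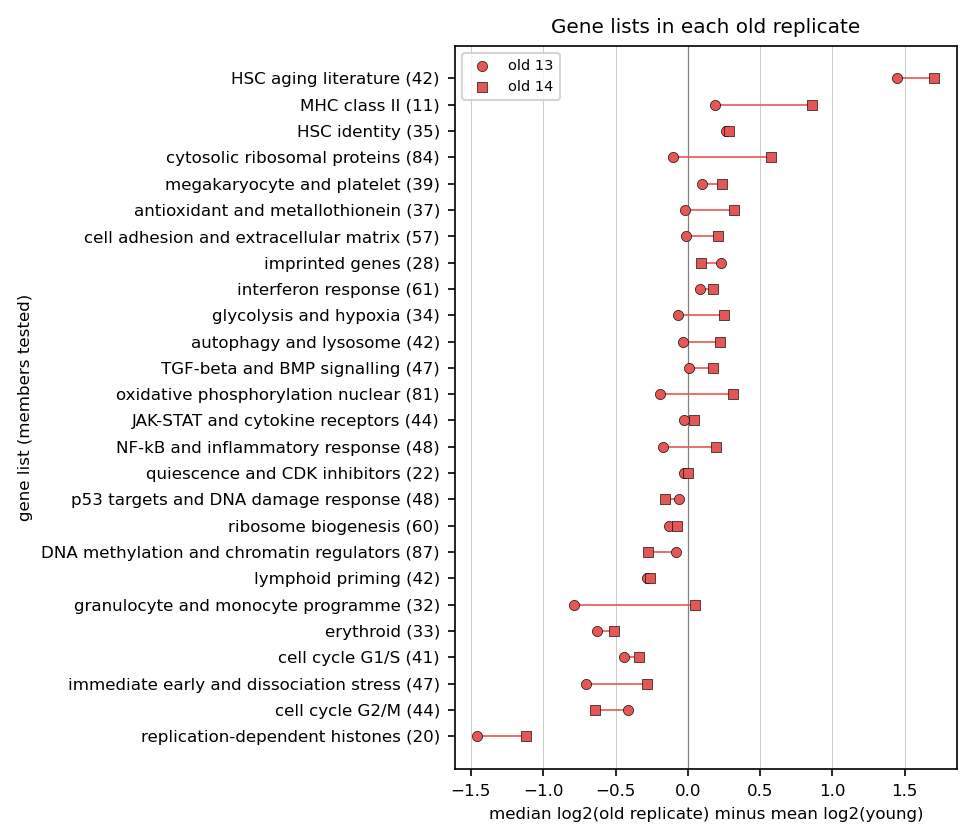
Median over the tested members of each gene list of the log2 value in an old replicate minus the mean log2 value of the young replicates, with a circle for old 13 and a square for old 14 and the number of tested members in brackets. The lists of cell cycle, histone and erythroid genes lie below 0 in both old replicates, whereas the cytosolic ribosomal protein list lies at -0.104 in old 13 and 0.573 in old 14.

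Single surface, matrix and signalling genes rose or fell. Of 57 cell adhesion and extracellular matrix genes 10 rose and 7 fell, and 18 rose and 9 fell when adjusted over the list alone; as the members went both ways, camera gave an adjusted p = 0.322 (0.0256 without young replicate 14). Besides Selp, Matn4 and Cldn5, the desmosomal cadherin Dsg2 rose from 532.5 ± 21.2 to 1847 ± 156.6. Of these, Selp, Matn4 and Dsg2 are also in the HSC aging list. Of 47 TGF-beta and BMP signalling genes 5 rose and 1 fell, with 7 and 1 when adjusted over the list alone (camera adjusted p = 0.3, with 0.0478 without young replicate 14 and 0.0267 among genes with a mean FPKM of at least 1). Bmpr1a, a type I BMP receptor, rose from 495 ± 62.2 to 2721 ± 488.3, its ligand Bmp4 from 187.2 ± 28.6 to 645.5 ± 24, and the co-receptor Neo1 from 1078 ± 105 to 3466 ± 304.4, and Col4a2, a basement membrane collagen, fell from 4639 ± 503.8 to 2288 ± 128. Of 44 JAK-STAT and cytokine receptor genes Osmr rose and Flt3 and Socs2 fell (camera adjusted p = 0.562), with 1 and 3 when adjusted over the list alone. Socs2, a feedback inhibitor of cytokine signalling, fell from 676.2 ± 62.6 to 250.5 ± 6.4. Of 48 NF-kB and inflammatory genes Osmr, Bcl3 and Tnfsf10 rose, 3 also when adjusted over the list alone, and the list had an adjusted p = 0.702, with 7.39e-06 downward without young replicate 13 and 0.00474 upward without young replicate 14. Of 61 interferon response genes only Rtp4, a chaperone protein, rose, from 967 ± 145.7 to 1896 ± 6.4, while Oas2, an antiviral synthetase, was 798.8 ± 93.7 and 439.5 ± 12.7 without passing. When adjusted over the list alone 1 rose (camera adjusted p = 0.139). The interferon list passed without old replicate 13 (0.0212), with no filter on low values (0.0321), with a mean FPKM of at least 1 (0.0387) and with quantile normalization, which was chosen after the data were seen (0.0449).

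Some detoxification and imprinted genes rose. Of 37 antioxidant and metallothionein genes 5 rose and 1 fell, with 8 and 1 when adjusted over the list alone. Gstm2, a glutathione transferase, rose from 444.2 ± 68.9 to 2358 ± 391.4, the metal-binding Mt1 from 697.8 ± 51.3 to 1873 ± 397, and the retinaldehyde dehydrogenase Aldh1a1 from 10146 ± 730.1 to 22691 ± 4315, whereas Hmox1, the haem-degrading enzyme, fell from 913.8 ± 78.1 to 501 ± 9.2. The list had an adjusted p = 0.00811, an adjusted p = 0.759 with an estimated correlation, 0.188 without young replicate 13, and 0.947 with a turned direction without old replicate 14. Of 28 imprinted genes 4 rose, namely Ndn, Dlk1, Asb4 and the row of Snrpn and Snurf, with 5 when adjusted over the list alone (camera adjusted p = 0.308, and 0.00179 among genes with a mean FPKM of at least 1). Dlk1, a Notch-like ligand, rose from 225.8 ± 40.7 to 718.2 ± 237.9. Of 34 glycolysis and hypoxia genes Epas1, the hypoxia-inducible factor HIF-2 alpha, rose from 237.8 ± 41.4 to 617.8 ± 27.9, and Hk2, hexokinase 2, was 2909 ± 8.1 and 4406 ± 262 (adjusted p = 0.0839), with 3 rising when adjusted over the list alone (camera adjusted p = 0.308, and 0.00109 without old replicate 13). Of 48 p53 target and DNA damage genes Perp, a p53 target of cell adhesion, rose from 145.8 ± 19.4 to 429 ± 154.9, Plk2, a polo-like kinase, was 1410 ± 588 and 3692 ± 529.6 (adjusted p = 0.0524), and 2 rose when adjusted over the list alone. The list itself pointed down, with 30 members below 0, a median of -0.107 and a camera adjusted p = 0.051. It passed without old replicate 13 (0.018), with median-ratio factors (0.0446), with the higher-numbered technical libraries (0.0454) and with the 8 libraries as independent (0.0222). Of 42 autophagy and lysosome genes 0 passed in limma or limma-voom, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.463, and 0.00319 without old replicate 13). Ctsl, a lysosomal protease, was 1768 ± 102.9 in young and 2701 ± 614.5 in old HSCs, and Lamp2, a lysosomal membrane protein, 10390 ± 2466 and 17043 ± 6596. Of 11 MHC class II genes 0 passed in limma or limma-voom over all genes, with 5 at an unadjusted p under 0.05, and 4 rose and 1 fell when adjusted over the list alone. H2-Eb1, a class II beta chain, was 1823 ± 22.6 in young and 3766 ± 1272 in old HSCs, and H2-Eb2 was 40.2 ± 3.9 and 130.5 ± 55.2. The class II list had an adjusted p = 0.0194, an adjusted p = 0.759 with an estimated correlation, 0.0732 without young replicate 13 and 0.182 without old replicate 14.

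Genes of translation and respiration differed between the old replicates. Of 84 cytosolic ribosomal protein genes 0 passed in limma or limma-voom and 0 had an unadjusted p under 0.05, although 83 had a fitted change above 0 and camera gave an adjusted p = 0.00329. The adjusted p was 0.827 with an estimated correlation, and without old replicate 14 the list turned to lower in old HSCs (adjusted p = 0.000127), and without young replicate 13 it did not pass (0.315). Rps12 was 1006 ± 118.8 in young and 1268 ± 178.2 in old HSCs, and Rpl38 was 2201 ± 257.7 and 2778 ± 561.1. Of 81 nuclear genes of oxidative phosphorylation 0 passed in limma or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.991, with 5.89e-08 upward without old replicate 13 and 3.29e-10 downward without old replicate 14), and the list lay at a median of -0.193 in old 13 and 0.309 in old 14 against the young mean. Of this list Cox7a1 was 6.2 ± 3.9 and 10.8 ± 1.1, and Ndufa11 1052 ± 99.3 and 1252 ± 308.3. The 5 most abundant rows were Eef1a1, the translation elongation factor, the mitochondrial row DQ539915, Cytb, Eef2 and Gpr56, none of which passed. Eef1a1 was 369785 in young 13, 458802 in young 14, 379878 in old 13 and 639014 in old 14. Only mt-Nd4 of the mitochondrially encoded list was matched by name, at 44929 ± 4920 in young and 48058 ± 2639 in old HSCs.

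Markers of other cells that a bone marrow sort could carry were measured in the same libraries, and 9 marker genes of all lists passed the test. Of 11 stroma rows matched and 9 tested, Col1a1 and Col3a1 fell, and Cxcl12, the most abundant, was 2938 and 1300 in young and 1461 and 986 in old HSCs. All 9 tested stroma genes had a fitted change below 0, with a median log2 fold change of -0.703. The summed stroma values were 6851 in young 13, 7341.5 in young 14, 3249 in old 13 and 3029.5 in old 14. Fewer stroma cells carried into the old sort cannot be told apart here from lower expression within HSCs. Among 7 red cell rows Slc4a1 and Car1 were among those that fell, and Car1, carbonic anhydrase 1, was 4924 and 7284 in young and 2753 and 1996 in old HSCs. Of 11 progenitor genes Flt3 and Cd34 fell, with Mpo as the most abundant. Of 9 tested endothelial genes Cldn5 and Kdr, a VEGF receptor, rose, while Tek, the most abundant, was 3537 and 3662 in young and 3752 and 3820 in old HSCs. The endothelial list had 5 of 9 tested genes below 0, with a median log2 fold change of -0.116. The dendritic list had Flt3 as its only gene that fell and Bst2 as the most abundant, at 2048 and 1770 in young and 2085 and 2546 in old HSCs. In limma and in limma-voom 0 genes passed in the lists of B cells, T and NK cells, neutrophils, macrophages, megakaryocytes or platelets, mast cells and basophils, and sex-linked genes, with 2, 3, 5, 6, 0, 0 and 0 at an unadjusted p under 0.05. The macrophage list had a median log2 fold change of -0.854, with 8 of 11 tested genes below 0. Their most abundant members were Cd79b at 1033, 1006, 1066 and 1195, Nkg7 at 1281, 2138, 696 and 983, S100a8 at 1092, 3535, 77 and 1547, Apoe at 15372, 14468, 17250 and 19479, Pf4, Prss34 at 165.5, 2772, 573 and 843, and Ddx3y at 3622, 3810, 3528 and 3678 in young 13, young 14, old 13 and old 14.

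**Figure D3:**
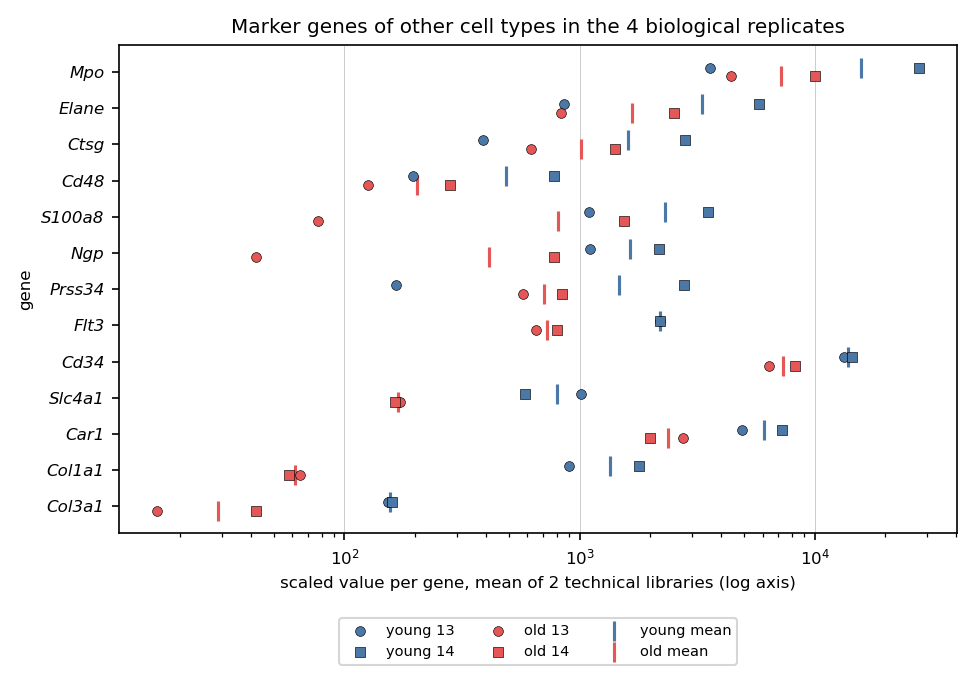
Scaled values (log axis) of 13 marker genes, chosen for display after their values were seen, in the 4 biological replicates, with a vertical tick at the mean of each age. Flt3, Cd34, Slc4a1, Car1, Col1a1 and Col3a1 separate the ages, while Mpo, at 27762 in young 14 and 3598 in young 13, and S100a8, at 77 in old 13 and 1547 in old 14, differ between replicates of 1 age.

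The technical libraries of a replicate were closer to each other than to any other library of the same age. A chi-square statistic of the reads over genes, divided by its degrees of freedom, was between 1.51 and 2.6 for the 4 technical pairs and between 26.7 and 78.3 for pairs of libraries from different biological replicates of 1 age. The lowest biological value was 10.3 times the highest technical value. Merging the technical libraries and counting them once in n had been set beforehand from the labels.

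The authors' deposited table gives its own fold change and FDR for the 24-month over the 4-month libraries. The authors' deposited table has 3173 genes with an FDR under 0.05, of which it marks 1338 as higher and 1297 as lower in old HSCs, and each of the 2635 marked genes has a summed FPKM of at least 1. Of the 467 genes called here, the authors' deposited table gives an FDR for 402, and all 402 have an FDR under 0.01 there, against 58 expected for unrelated lists of these sizes among the 15270 tested genes with an FDR. The other 65 are rows with HNG, HAG or HND names, for which the authors' deposited table lists no FDR. All 402 have the same direction in both. Across 15270 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those fitted here had a Pearson correlation of 0.989. Both rest on the same libraries, so neither is independent of the other. Of the genes with an FDR under 0.05 in the authors' deposited table that were tested here, 84.6% had both old replicates on one side of both young replicates. Among all tested genes this share was 42.1%. The authors' genes were selected on the same libraries, so the difference follows at least in part from that selection.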

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

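A single prior variance, a robust prior and quantile normalization were chosen after the data were seen, and the other settings before. Fits in edgeR and DESeq2, with TMM or size factors on counts, had been intended and were not run because the values are scaled. The 467 changed genes (368 higher, 99 lower) became 477 with limma-voom on approximate reads, 450 with median-ratio factors, 344 with library totals, 484 with the stricter filter, 461 and 467 with pseudocounts of 0.1 and 1, 414 with at least a 2-fold change, 314 with the higher-numbered technical libraries, 320 with a single prior variance, 608 with a robust prior and 425 with quantile normalization. No gene called in both fits changed direction under any setting. The share of higher genes was 76.2% with median-ratio factors, 80.5% with library totals and 72.5% with quantile normalization, against 78.8%. With no filter on low values limma called 0 genes (0 higher, 0 lower, 0 markers, 0 shared with the authors' calls), with 2943 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0551; the prior degrees of freedom were 2.37 there, against 4.95. A mean FPKM of at least 1 gave 302 genes (237 higher, 65 lower), and an adjusted p under 0.01 gave 117 (109 higher, 8 lower, 3 markers, 106 shared with the authors' calls), as a stricter threshold must give fewer. The lower-numbered technical libraries gave 302 genes (55 lower, 265 shared with the authors' calls), the higher-numbered ones 52 lower genes, and a single prior variance 56 lower genes, 3 markers and 258 shared calls. The cause was not tested for the FPKM filter, the single libraries and the single prior variance. Entering the 8 technical libraries as independent gave 3690 genes (2230 higher, 1460 lower, 31 markers, 2309 shared with the authors' calls), as it counts each biological replicate more than once.

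With the replicate number as a block the fit called 2766 genes (1698 higher, 1068 lower, 46 markers, 2270 shared with the authors' calls) and kept all 467. The labels do not say that equal numbers share an animal, a litter or a day, and 2 pairs are too few to show it. The deviations of equal-numbered replicates from their age means correlated over genes at 0.544, and the second principal component (34.8% of the variance) separated 13 from 14 at both ages.

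Leaving out 1 replicate leaves an age with a single sample, which is assumed to vary like the other age. The count of changed genes was then 0 to 274, of higher genes 0 to 206, of lower genes 0 to 68, of markers 0 to 9 and of calls shared with the authors 0 to 232. Both counts of 0 came without an old replicate, with 3669 (without old 13) and 1933 (without old 14) genes at an unadjusted p under 0.05. The prior degrees of freedom were 2.92 in both, against 8.16 and 8.34 without a young replicate. Log2 fold changes that turned then ranged from -0.12 to 0.63 for Eef1a1, -0.03 to 0.5 for Eef2, -0.02 to 0.49 for Ndufa11, -0.06 to 0.57 for Ndufc2, -0.06 to 0.44 for Ndufa7 and -0.01 to 0.21 for mt-Nd4. For lists whose direction turned, camera's adjusted p ranged from 0.00602 to 0.719 for quiescence, 1.28e-19 to 0.344 for granulocytes and monocytes, 1.8e-19 to 0.315 for cytosolic ribosomal proteins, 3.29e-10 to 0.523 for oxidative phosphorylation, 0.00109 to 0.846 for glycolysis and hypoxia, 7.39e-06 to 0.358 for NF-kB, 1.09e-31 to 0.213 for immediate early genes, 2.2e-06 to 0.947 for antioxidant genes, 0.0256 to 0.652 for cell adhesion, and 0.00319 to 0.61 for autophagy. The cause was not tested.

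Of 26 gene lists 15 passed with camera, 13 to 18 under the other fits, 0 with an estimated correlation and 0 with fry, which tests for a shared direction against no change. Fry's mixed test, which lets members go either way, passed for some lists. It gave an adjusted p = 0.00684 for HSC aging, G1/S, cell adhesion and JAK-STAT. Other lists did not pass with it, such as granulocytes and monocytes (0.693) and ribosome biogenesis (0.553). Other turned directions all had an adjusted p of at least 0.6. Oxidative phosphorylation turned with median-ratio factors (0.866), library totals (0.892), the stricter filter (0.995) and the higher-numbered libraries (0.961). Quiescence turned with no filter (0.76), the FPKM filter (0.997), the lower-numbered libraries (0.984), fry (0.728) and quantile normalization (0.752). NF-kB turned with no filter (0.928), the stricter filter (0.711), the FPKM filter (0.656) and fry (0.728), and JAK-STAT with fry (0.6). With quantile normalization the log2 fold changes of Eef1a1, DQ539915 and Gpr56 were 0 to 2 digits, that of Cytb -0.08 and that of mt-Nd4 -0.01. Quantile normalization gives rows of equal rank the same value. Eef1a1 had the highest value in every replicate and DQ539915 the next highest, so the method itself sets their change to 0. For the other turned directions the cause was not tested. Over all settings with every replicate, 1934 of 2243 values of single genes and lists kept their direction and side of the threshold, 178 lost the threshold, 112 gained it and 19 turned. The filter left out genes of low value: 18318 of 38172 reached a scaled value of 10 in at least 2 replicates, and the others were not tested. Whether more depth would bring in more of them was not tested.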

Other observations

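The tests of globins, of both old replicates for ribosomal protein genes, of the young replicates for the G2/M list, and of Cd34, Flt3, Car1, Klf1 and Gata1 were chosen only after their results had been seen, as were the genes of this paragraph. The proteases Prss34, Mcpt8 and Elane had their highest values in young 14. Prss34 was 165.5 in young 13, 2772 in young 14, 573 in old 13 and 843 in old 14, Mcpt8 was 72.5, 1152.5, 263.5 and 332, and Elane was 858, 5774.5, 834 and 2521.5. Ngp, a granule protein of maturing neutrophils, was 1112.5 and 2170 in young and 42 and 779.5 in old HSCs. The collagen gene Col1a2 was 1462 and 2511.5 in young and 747 and 822.5 in old HSCs (adjusted p = 0.055), and C1qa, a complement gene of macrophages, was 177.5 and 186.5 against 84.5 and 80.5 (adjusted p = 0.0615).

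Cytosolic ribosomal protein genes lay above the young mean in old 14 by a median log2 difference of 0.573 (84 of 84 genes). Old 13 did not show this rise, with a median of -0.104 and 14 of 84 genes above the young mean. The genes of the list vary together (estimated correlation 0.8973), so they are not separate observations. With the old replicates this far apart, an effect of age is not decided. After all replicates were set to equal totals, a test written before its result was seen, the median in old 14 was 0.483. The deposited totals already lay between 40.7 M and 44.2 M, so that step could change the median little and decides nothing by itself. With old 14 as the only old replicate, the median log2 fold change of all tested genes was 0.065. A factor shared by all genes moves the list and the other genes alike, so it cannot raise the list above them. A small median over all genes may itself follow from the authors' scaling, so it does not show that the scaling was right. A better recovery of short transcripts in old 14 stays open: 205 other genes matched on length and level had a median of 0.272 (quartiles 0.096 and 0.434), and they reached only 0.221 of the level of the list.

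Fitted changes of the G2/M and histone lists had medians of -0.53 and -1.51 in old HSCs, although only 1 of 44 and 2 of 20 genes passed and both lists missed the threshold with an estimated correlation (adjusted p = 0.299). For the histones, a lower recovery of RNAs without a polyA tail in the old libraries stays open, since 9 other such RNAs had a median of -0.324 with quartiles of -0.432 and 0.155, a test written before its result was seen. As to myeloid progenitors in the young sort, Mpo was 7.72 times higher in young 14 than in young 13 while the G2/M median differed by 0.012. The G2/M list thus did not follow Mpo between the young replicates. These replicates also differed by a median log2 difference of 1.53 in the stress list, so a single pair cannot decide this. Fewer early multipotent progenitors in the old sort might account for part of the change, as Flt3 and Cd34 both fell, Cd34 by a log2 fold change of -0.941. The make-up of the sort changes together with age in this design, so this cannot be separated from slower division of old HSCs.

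Of 33 tested erythroid genes, with a median log2 fold change of -0.347, 11 fell, with a median of -1.703 among these. The sort was set to take cells that carry Kit and Sca-1 and lack lineage markers, and how well it kept out other cells was not tested here. Mature red cells in the young sort would lower the globins too. The 3 globin rows had a median of -0.152, which is smaller than the fall of those 11 genes but lies nearer to the median of the whole list. The globins differed between the old replicates, with a median of -0.629 in old 13 and 0.324 in old 14 against the young mean, so this explanation stays open. Fewer erythroid progenitors in the old sort could also account for the change, as Car1, Klf1 and Gata1 all fell, the smallest fall being -1.08, and lower expression within HSCs cannot be told apart from it because the make-up of the sort changes together with age.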
